A study of Mus musculus with 6 samples.

How the data were processed

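Expression was measured on 6 Agilent 1-colour arrays, 1 for each combination of the olfactory bulb, hippocampus or cortex with saline or PAMAM (0.15 mg/kg), from male BALB/c mice aged 8 weeks whose tissue was taken at 24 h. Per the labels' protocols, RNA was extracted with QIAGEN RLT buffer, cleaned with RNeasy mini kits, treated with DNase I, checked on an Agilent Bioanalyser and labelled with Cy3 by Agilent's One-Color protocol. Per the series' design text, the RNA on each array was pooled from 6 independent experiments. The labels do not say whether the 3 regions of a treatment came from the same mice. Groups were taken from the labels.

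The deposited scanner files hold spot intensity on a linear scale (background-corrected processed signal, mean signal and local background), made with Agilent Feature Extraction 10.7.3.1 from a G2505C scanner on array design 028005, per the file headers. All 6 arrays lie on one slide scanned together, so no slide or scan differed between groups. The saline and PAMAM arrays of the hippocampus lie in different slide rows, and the pairs of the other regions in one. Each array holds 62976 spots, of which 59305 are non-control spots of 55681 probes. Of these probes 399 are spotted 10 times and 33 are spotted 2 times. The authors also deposited a table of log2 values for the same arrays, whose scale, centring and direction are not given in the sources used here. Its columns have medians of -0.0906 and -0.0617 (olfactory bulb, saline and PAMAM), -0.0458 and 0.0252 (hippocampus) and 0.0432 and 0.0347 (cortex). Set against the scanner values, the table equals the 75th-percentile-scaled log2 values minus the probe's median over the arrays, with r from 0.9999 to 1 over 29553 probes and a largest residual of 0.0233. The largest probe median in it was 5e-07 over 55666 probes. Log2 scale, centring by probe and direction were thereby settled from the values, and what remains unknown is how the authors treated repeated spots and any filter.

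For the main values, log2 of the processed signal was taken and each array's 75th percentile over non-control spots subtracted. That percentile was 679.1 and 709.6 in the olfactory bulb (saline and PAMAM), 640.5 and 547.1 in the hippocampus and 541.6 and 452.0 in the cortex. Spots with an outlier mark were dropped, which removed 15 probes, and spots of a probe were averaged. A gene is represented by its probe with the highest mean over the arrays, and values of other measured probes are given for many of the named genes. Gene names came from the array files, updated through RefSeq accessions paired with symbols (GRCm38.p6, used for names only): 27235 of 55681 probes matched, 2838 of them with a changed symbol, and 28446 kept the name in the file, which can be old. After dropping outliers 35010 symbols remained. Probe coordinates are those of the files, build mm9.

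A gene counted as measured in a region where its probe was well above background on both arrays and saturated on neither, and as different at a log2 difference of at least 1 (2-fold). Where only 1 array of a pair was well above background, the difference is given as a bound: the brighter value over the higher of the dim probe's own value and the lowest value among probes well above background on that array. Of genes well above background on 1 array only, 862 were higher and 162 lower in the olfactory bulb, 350 and 716 in the hippocampus and 613 and 708 in the cortex. By a bound of at least 2-fold these were 24 and 105, 209 and 18, and 84 and 151, a split that depends on the lowest such value of each array. Spot noise was taken from the repeated probes after spots with an outlier mark were dropped. Probes with 1 spot have no repeats against which an odd spot would show, so the noise of their genes may be understated.

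In all, 32 gene lists were fixed before the data were examined: immediate-early, heat shock, unfolded protein response, glucocorticoid-responsive, circadian clock, BDNF and TrkB, oxidative stress and NRF2, cytokine and NF-kB, interferon, p53 and apoptosis, lysosome, cholesterol, mitochondrial and ribosomal genes, glutamate and GABA receptor genes, neuropeptides, and markers of cell types and neighbouring tissues. They have 754 entries, of which 750 are on the array. The median log2 difference of members well above background on at least 1 array of the pair was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list with at least 5 such members stands apart below the 0.5th or above the 99.5th percentile. Counts of list members given below follow this rule of at least 1 array unless both arrays are named. This describes these arrays and is not a p-value. By these limits, 0.96 of the 96 list and region pairs would stand apart by chance if lists behaved as random ones, and 32 did. Random members were drawn one by one, while genes of a list can vary together, so more lists can stand apart without any effect of treatment. With 1 array per group, how many would do so cannot be shown. Lists of liver transcripts and of the cold-inducible genes Rbm3 and Cirbp were added after seeing the data.

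The difference shared by the regions was tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3) on all 6 arrays with region as a block, which leaves 2 residual degrees of freedom, over 23337 genes well above background on at least 3 arrays, with Benjamini-Hochberg adjustment and a threshold of 0.05. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Tested on simulated data built from these arrays, the shared fit over 23337 genes recovered 89 of 100 genes changed by a log2 of 1 and 96 of 100 changed by 2, with 11 false calls. The simulated noise used variances already drawn together across genes by limma, so this recovery is likely higher than on the real arrays. In the real limma fit Isoc2b differed by 1.02 with an adjusted p of 0.739. A lack of calls there thus does not show that no gene differed. The list step placed 0 of 32 lists apart after shuffling in each region, and found 32 lists shifted by 0.2 in the olfactory bulb (24891 genes), 31 in the hippocampus (23968 genes) and 27 in the cortex (22966 genes). The count step found 200 of 200 genes changed by 1.5 and 0 others in each region. A change of 1.5 lies above the threshold of 1, so this checks the counting alone. It gives no rate of false calls on the real arrays.

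Genes named in the text were chosen by a rule fixed before the data were examined: per region the 10 genes with the largest difference in each direction among those measured on both arrays and brighter than the median detected probe on at least 1 of them, leaving clone names, predicted genes and accessions unnamed; up to 4 members with the largest difference of each list that stands apart, and any list member at least 2-fold different; up to 3 genes per direction by the largest bound; genes at least 2-fold different in all 3 regions; and Bdnf, Ntrk2, Creb1, Hmox1, Il1b, Tnf, Il6, Ccl2, Gfap, Aif1, Fos and Arc. The filter on clone names and accessions was widened to further accession styles after one such name showed among the largest differences. A few genes that the rule selects are not reported here. Genes leading the shared fit, genes shared by pairs of regions and further list members were named after their values were seen.

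Alternatives were median centring of detected probes, quantile normalisation, normexp background (offset 50) on mean and background signals with quantile normalisation, the deposited log2 table, no filter on dim probes, brighter genes only, the median of all probes of a gene, thresholds of 1.5-fold and 3-fold, a requirement of 3 times the scanner's error, list members measured on both arrays, wider percentile limits, and for limma no region block and leaving out each region. Counts without the choroid plexus, meningeal and red blood cell lists were added after seeing the data.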

Results

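Gene expression was measured on microarrays in 3 brain regions of male BALB/c mice, an inbred laboratory strain, aged 8 weeks. Tissue was taken 24 h after one dose into the nose of saline or of PAMAM dendrimers, highly branched polyamidoamine polymers that carry drugs or nucleic acids, at 0.15 mg/kg. The olfactory bulb, the hippocampus and the cortex were studied, which with the saline and PAMAM treatments makes 6 groups. Each group has 1 array, hybridised with RNA pooled from 6 independent experiments. A difference between PAMAM and saline within a region is thus a difference between 2 arrays with no replicate check, and no p-value is given for it. All differences are log2 values, PAMAM minus saline, and the number of arrays limits their precision.

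Of the 59305 non-control spots on an array, 36614 and 39057 were well above background in the olfactory bulb (saline and PAMAM), 36762 and 34872 in the hippocampus, and 34354 and 34134 in the cortex, and 0 were saturated. Spots of one probe on one array differed by a median SD of 0.07 (log2), and for brighter genes a difference between arrays from this spot noise alone had an SD of 0.08 in the olfactory bulb and 0.09 in the other regions. This leaves out labelling, hybridisation, animals and outlier spots, which were dropped before. The gene counts given below for spot noise may thus be too low for probes with 1 spot. The region labels were checked with marker genes. Olfactory bulb neuron markers were higher in the olfactory bulb than the mean of the other regions by a median of 3.57 in the saline arrays (20 of 20 members) and 3.58 in the PAMAM arrays. Hippocampal markers were higher in the hippocampus by 2.35 (19 of 19) and 2.27, and cortical markers in the cortex by 1.29 (16 of 20) and 1.03. Regions differed far more than treatments did: in the saline arrays, 11.4% of genes differed at least 2-fold between olfactory bulb and hippocampus, 11.5% between olfactory bulb and cortex and 4.55% between hippocampus and cortex, against 0.258%, 0.649% and 0.768% between PAMAM and saline in the olfactory bulb, hippocampus and cortex.

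The first comparison asked how the dendrimer dose left expression in the olfactory bulb, the region nearest to the nasal cavity. Immediate-early genes, which neurons switch on within minutes of activity, were lower with PAMAM there: 18 of 25 measured members were lower, with a median of -0.56, below every one of 10000 random lists matched on expression. Egr4 differed by -1.49, Junb by -1.36, Nr4a3 by -1.24, the activity-dependent factor Npas4 by -1.13, Arc by -1.11 and Fos by -1.04, while Jun was higher by 0.45. Junb and Nr4a3 are dim there, that is, not above the median detected probe on either array. Several genes of major urinary proteins, pheromone carriers made mostly in the liver, were lower too, with Mup18 at -2.89, Mup17 at -2.81, Mup9 at -2.64, Mup19 at -2.55 and Mup4 at -2.25. The alpha-1 antitrypsin genes Serpina1c (-1.34), Serpina1a (-1.34, and -1.38 on another probe) and Serpina1e (-1.27, but -0.51 on another probe) were lower beside them. The Mup and the Serpina1 copies are near-identical, so which copy a probe reads is uncertain.

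**Figure D1:**
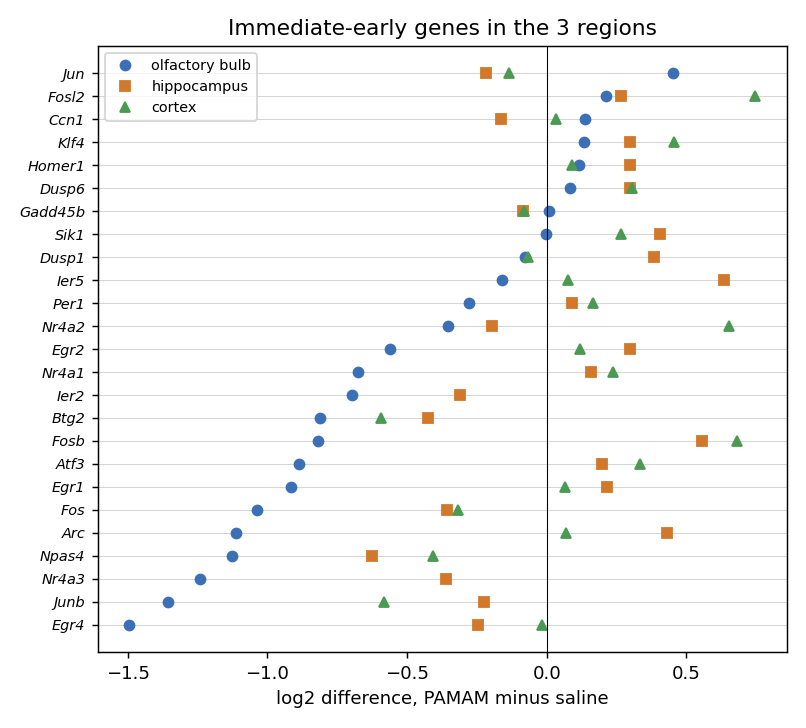
Log2 difference between PAMAM and saline (x axis) of each immediate-early gene measured on both olfactory bulb arrays (y axis), with 1 point per region where both arrays of that region measured it. Egr4 (-1.49), Junb (-1.36) and Arc (-1.11) lie far to the left in the olfactory bulb, and Arc lies at 0.43 in the hippocampus and 0.07 in the cortex.

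Genes of protein folding were higher in the olfactory bulb. Of 18 heat shock genes 17 were higher (median 0.16), led by the small chaperone Hspb1 at 0.41, Hspa1a at 0.32 and Hsph1 at 0.31. Of 21 genes of the unfolded protein response, the answer of the endoplasmic reticulum to misfolded protein, 15 were higher (median 0.23), with Sdf2l1 at 0.68, Hyou1 at 0.53, Pdia4 at 0.47 and the chaperone Hspa5 at 0.43, while Trib3 was at -0.45. Glucocorticoid-responsive genes were higher in 14 of 20 (median 0.12), with Zbtb16 at 0.44, Map3k6 at 0.43 and Fkbp5 at 0.34. Microglia markers were slightly higher, with 17 of 24 (median 0.07), among them Cd53 at 0.33 and Fcrls at 0.20. These 4 lists lay above their matched random lists. Below them lay, besides the immediate-early genes, oligodendrocyte and myelin markers (16 of 22 lower, median -0.11; Opalin -0.31, Tspan2 -0.25, and -0.07 on another probe, but Ermn 0.32, and 0.05 on another probe), striatal neuron markers (12 of 15 lower, median -0.14; the dopamine receptor Drd2 -0.69, Adora2a -0.31, but Pde10a 0.70 and 0.72 on another probe), circadian clock genes (11 of 19 lower, median -0.10; Dbp -0.57, Nr1d1 -0.52, but Npas2 0.54 and Cry1 0.49) and cholesterol synthesis genes (18 of 24 lower, median -0.09; Hmgcs1 -0.26, Sqle -0.26). Quantile normalisation ended the place of the clock list (-0.09; with the median of all probes -0.07, also not apart) and the cholesterol list (-0.08), and brighter genes only that of the striatal list (-0.05) and the microglia list (0.07), which normexp background also ended (0.06). Of the genes named in these lists, Drd2, Cd53, Npas2, Cry1 and Opalin are among the dim ones. Choroid plexus (median -0.06), meningeal (-0.07) and red blood cell markers (0.04) did not stand apart in the olfactory bulb.

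The largest higher values among brighter genes of the olfactory bulb were those of Dct, an enzyme of melanin synthesis (3.0), the monocarboxylate transporter Slc16a7 (2.60), the respiratory chain gene Uqcrc1 (1.75) and Isoc2b (1.35), followed by Prb1 (0.76), Pemt (0.73), Pde10a (0.70), Sdf2l1 (0.68), Wif1 (0.62) and Cmya5 (0.57). The largest lower value was that of Blm, a DNA helicase, at -6.99, which rests on 1 spot per array. Other probes of Pemt lay between -0.27 and 0.11, and that of Cmya5 at -0.03. Among genes well above background on 1 of the 2 arrays, H2ac8 was at least 58.3-fold, Plxna4os1 at least 23.8-fold and Mup20 at least 14.6-fold lower with PAMAM, and the odorant receptors Olfr1215, Olfr429 and Olfr906 were at least 5.94-fold, 3.42-fold and 2.60-fold higher. In all, 12 of 23288 measured genes were at least 2-fold higher and 48 at least 2-fold lower (6 and 19 with normexp background), and spot noise alone gives 15.7 such genes, all of them dim. Of 10 of these genes with another measured probe, 4 differed at least 2-fold the same way on it.

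The second comparison put the same question to the hippocampus. There the choroid plexus markers, genes of the epithelium that makes cerebrospinal fluid, were higher with PAMAM in 21 of 21 members (median 0.72): F5 differed by 0.98, the bicarbonate transporter Slc4a5 by 0.97, Kcne2 by 0.91 and Sostdc1 by 0.91, and other probes of F5, Slc4a5 and Sostdc1 gave 0.95, 1.18 and 0.82. Red blood cell markers were higher in 9 of 9 (median 0.49; Slc4a1 0.91, Hbb-b2 0.58, Alas2 0.51), and thalamic neuron markers in 9 of 11 (median 0.41; Tnnt1 1.52, Slitrk6 0.98, Prkcd 0.70). Cortical neuron markers were higher in 14 of 19 (median 0.18; Rspo1 0.77, Lamp5 0.62) and hippocampal neuron markers lower in 16 of 19 (median -0.19; Cabp7 -0.39, Wfs1 -0.32, Zbtb20 -0.29). Meningeal markers did not stand apart (median -0.06). Of the genes named here, Slc4a1 and Slitrk6 are among the dim ones.

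Beside these markers, protein folding genes were higher in the hippocampus. All 18 heat shock genes were higher (median 0.21), with Hspb1 at 0.90, Cryab at 0.47, Hspb8 at 0.39 and Hsph1 at 0.38, and 18 of 21 genes of the unfolded protein response (median 0.24), with Sdf2l1 at 0.88, Manf at 0.71, Hspa5 at 0.63 and Creld2 at 0.55. Glucocorticoid-responsive genes were higher in 14 of 20 (median 0.08), among them the cell cycle inhibitor Cdkn1a at 1.31, Plin4 at 0.35 and Tsc22d3 at 0.25. Immediate-early genes were mixed, with 14 of 25 higher (median 0.16, mean 0.05): Ier5 was at 0.64, Fosb at 0.56 and Arc at 0.43, against Npas4 at -0.63, Btg2 at -0.43, Fos and Nr4a3 at -0.36 and Ier2 at -0.31. Fos was at -0.32 in the cortex. Oligodendrocyte markers were higher in 18 of 23 (median 0.09), with the myelin gene regulator Myrf at 2.18, Enpp2, which the choroid plexus also expresses, at 0.63 and Olig2 at 0.30. Myrf, far above the median of its list, is dim. Together 9 lists lay above and 1 list, the hippocampal markers, below matched random lists. With normexp background the hippocampal medians of immediate-early genes (0.06) and glucocorticoid-responsive genes (0.07) no longer stood apart.

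The largest higher values among brighter hippocampal genes were those of the vomeronasal receptor Vmn1r173 (3.85), the complexin Cplx4 (3.16), the transporter family gene Slc23a3 (2.40), Fam151b (2.01), Csf2rb2 (1.77), Stk32c (1.72), the atrial myosin light chain Myl4 (1.67), Borcs5 (1.60), Tnnt1 (1.52) and the membrane repair gene Dysf (1.43). The stress hormone gene Crh was higher by 1.23 and, on dim probes, Eomes by 1.19 and the metalloproteinase inhibitor Timp1 by 1.83. Another probe of Csf2rb2 gave -0.44. The largest lower values were those of Mup18 (-1.56), Mup19 (-1.53), Ecel1 (-0.89), the sodium and calcium exchanger Slc8a3 (-0.80), Cbln1 (-0.69), Nudt11 (-0.68), Mri1 (-0.64), Serpina1a (-0.64, but -0.10 on another probe), Npas4 and Ly6g6e (-0.62). The hypothalamic peptide gene Pmch, which is dim, differed by -1.17. On 1 of the 2 arrays only, Lcn10, Olfr747 and Tmem150b were at least 28.1-fold, 18.5-fold and 16.1-fold higher, and Mup20, Slc2a9 and Col2a1 at least 2.85-fold, 2.68-fold and 2.48-fold lower. In all, 130 of 22326 measured genes were at least 2-fold higher and 15 lower (46 and 4 with normexp background), against 8.83 from spot noise. Of 15 of these with another measured probe, 2 differed at least 2-fold the same way on it. Among brighter genes the counts were 29 higher and 3 lower of 13609.

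The third comparison put the question to the cortex. Choroid plexus markers were higher there in 18 of 19 members (median 1.16, and 0.78 over the 13 members measured on both arrays), with the thyroid hormone carrier Ttr at 2.71, the folate receptor Folr1 at 1.39, the potassium channel Kcnj13 at 1.22 (1.09 on another probe) and the water channel Aqp1 at 1.22. Sostdc1 was at 1.64 on its brighter probe and at -0.56 on another. Folr1, Aqp1 and Sostdc1 are dim in the cortex. Meningeal and fibroblast markers were higher in 21 of 22 (median 0.71), with the matrix genes Ogn at 1.29 and Dcn at 0.95, the retinoic acid enzyme Aldh1a2 at 1.18 and Slc13a4 at 1.15. Red blood cell markers were higher in 7 of 9 (median 0.49; Hbb-bt 0.82, Hbb-b2 0.69), and endothelial markers in 18 of 23 (median 0.18; Vwf 0.60, Cdh5 0.50, but Tek -0.59), the latter no longer apart with brighter genes only (0.16). Hippocampal neuron markers were higher in 15 of 17 (median 0.29; Spink8 0.81, Pkp2 0.71, Cpne7 0.65), and olfactory bulb neuron markers lower in 13 of 17 (median -0.30; Calb2 -1.06, Trh -1.04, Dlx6 -1.01). Without the dimmer genes, that last median was -0.04 and did not stand apart. Of the endothelial genes named, Cdh5 and Tek are dim too.

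**Figure D2:**
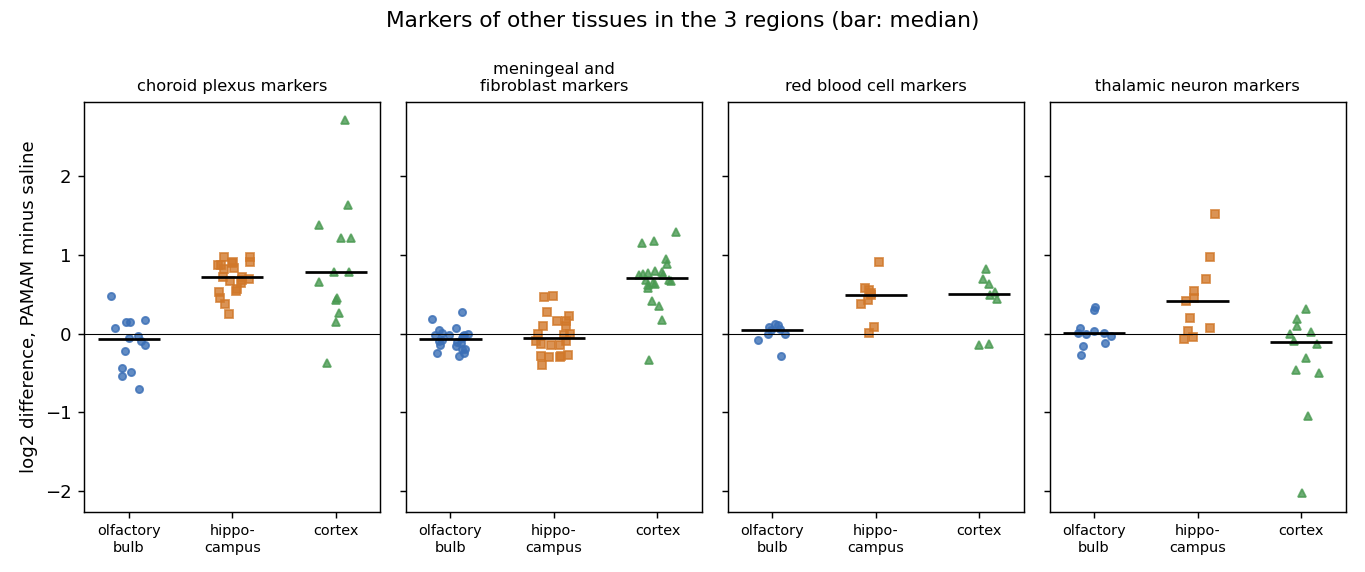
Log2 difference between PAMAM and saline (y axis) of markers of choroid plexus, meninges, red blood cells and thalamic neurons in the 3 regions (x axis); each point is a gene well above background on both arrays of the pair and each bar the median of these points. Choroid plexus markers centre on 0.72 in the hippocampus and 0.78 in the cortex against -0.08 in the olfactory bulb, and meningeal markers on 0.71 in the cortex alone.

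Beside these markers, heat shock genes of the cortex were higher in 17 of 18 (median 0.26; Hspb1 1.14, Hspb8 0.48, Chordc1 0.45, Hspa1a 0.41), and genes of the unfolded protein response in 15 of 21 (median 0.16; Sdf2l1 0.89, Pdia4 0.74, Creld2 0.66, Hspa5 0.60). Over the median of all probes of a gene, the latter median was 0.11 and did not stand apart. Reactive astrocyte genes were higher in 15 of 19 (median 0.34), with Hspb1, Emp1 at 0.93, the complement inhibitor Serping1 at 0.83 (1.10 on another probe) and Sphk1 at 0.71. Gfap, the astrocyte filament, was at 0.47, but its other probes ranged from -0.10 to 0.64; it was at 0.10 in the olfactory bulb (0.02 on others) and 0.06 in the hippocampus (-0.16 to -0.12 on others). Glucocorticoid-responsive genes were higher in 14 of 20 (median 0.19; Cdkn1a 1.59, Fkbp5 0.67, Map3k6 0.39). Microglia markers were higher in 19 of 24 (median 0.15; Cd86 0.61, C1qa 0.41, but Laptm5 -0.40, and -0.43 on another probe) and pan-neuronal genes in 16 of 19 (median 0.16; Gap43 0.30, but Syt1 -0.29), and both lists lost their place under quantile normalisation (0.10 and 0.05), with normexp background (0.09 and 0.05) and with the median of all probes (0.08 and 0.09), and the microglia list also over the members measured on both arrays (0.13). Oligodendrocyte markers were lower in 15 of 22 (median -0.07; Opalin -0.63, Mog -0.35, but Apod 0.44 and Mbp 0.47, with other probes of Mbp from -0.41 to 0.03). Of the genes named in these lists, Cd86, Emp1 and Hspb8 are among the dim ones. In all, 11 lists lay above and 2 below matched random lists. For several lists the cortical random medians were themselves positive, at 0.09 for pan-neuronal and 0.06 for heat shock genes. Ribosomal protein genes were higher in 36 of 38 there without standing apart (median 0.09, random median 0.09). Counts of higher members thus overstate the rise of such lists in the cortex.

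Among brighter cortical genes, the largest higher values were those of Tmem156 (3.16), Ttr (2.71), Slc23a3 (1.82), Zfp692 (1.65, but -0.11 on another probe), Srp54b (1.60), Cdkn1a (1.59), Plekhg4 (1.55), the retinoic acid degrading enzyme Cyp26b1 (1.40), the activin subunit Inhba (1.30) and Ogn (1.29). Ptgs2, an inducible enzyme of prostaglandin synthesis, was higher by 1.06. The largest lower values were those of the oxytocin gene Oxt (-3.47), Tmlhe (-3.43, but 0.04 on another probe), Scd4 (-3.03), Tnfrsf13b (-1.94, but -0.34 to -0.23 on others), Slc22a13 (-1.91), Lbhd2 (-1.66), Ccl19 (-1.41, but 0.16 on another), Dlk1 (-1.25, and -0.75 on another), the clock gene Ciart (-1.01) and Ern1 (-0.95, but -0.36 on another). Among dimmer genes, a further list member at least 2-fold lower was the thalamic Gbx2 (-2.03). Whether the cortex samples differed in neighbouring tissue was not tested for Oxt or Gbx2. On 1 of the 2 arrays only, Gpr174, Gcnt4 and Rbm31y were at least 13.2-fold, 9.0-fold and 6.62-fold higher, and Olfr781, the vasopressin gene Avp and Stap1 at least 28.7-fold, 16.4-fold and 15.7-fold lower. In all, 76 of 21601 measured genes were at least 2-fold higher and 90 lower (45.8% higher), against 8.82 from spot noise. The split depended on the scaling: quantile normalisation gave 97 and 65 (59.9% higher) and normexp background 24 and 19 (55.8% higher). Without the choroid plexus, meningeal and red blood cell lists, an alternative chosen after seeing the data, the cortex gave 68 and 90, and the other regions kept counts of 12 and 48 and of 130 and 15. Of 23 genes with another measured probe, 4 differed at least 2-fold the same way on it.

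Genes named in advance for neurotrophin signalling, oxidative stress and inflammation were read in every region. Bdnf, the growth factor that signals through TrkB, was higher by 0.15 in the olfactory bulb, 0.56 in the hippocampus and 0.97 in the cortex (mm9 chromosome 2, probe at 109566961 to 109567020). Its receptor gene Ntrk2 differed by 0.11, 0.02 and 0.07, with other probes up to 0.31, 0.19 and 0.16, and Creb1 by 0.15, 0.38 and -0.09, with other probes of Creb1 from -0.54 to 0.16 in the olfactory bulb, at 0.07 in the hippocampus and at -0.43 in the cortex. The BDNF and TrkB list as a whole had medians of -0.04, 0.01 and 0.07. Hmox1, a haem-degrading enzyme induced by oxidative stress, differed by 0.13, 0.12 and -0.17, with another probe at -0.49, -0.10 and -0.37, and oxidative stress and NRF2 targets had medians of 0.01, 0.01 and 0.09. Tnf, Il6 and Il1b were not well above background on any array, and Ccl2 was measured in the olfactory bulb alone (-0.14). Cytokine and NF-kB genes had medians of 0.00, 0.02 and 0.00 and interferon-stimulated genes of 0.00, 0.07 and 0.08. The microglial gene Aif1 differed by -0.09, 0.00 and 0.18. None of these 4 lists stood apart from matched random lists in any region.

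**Figure D3:**
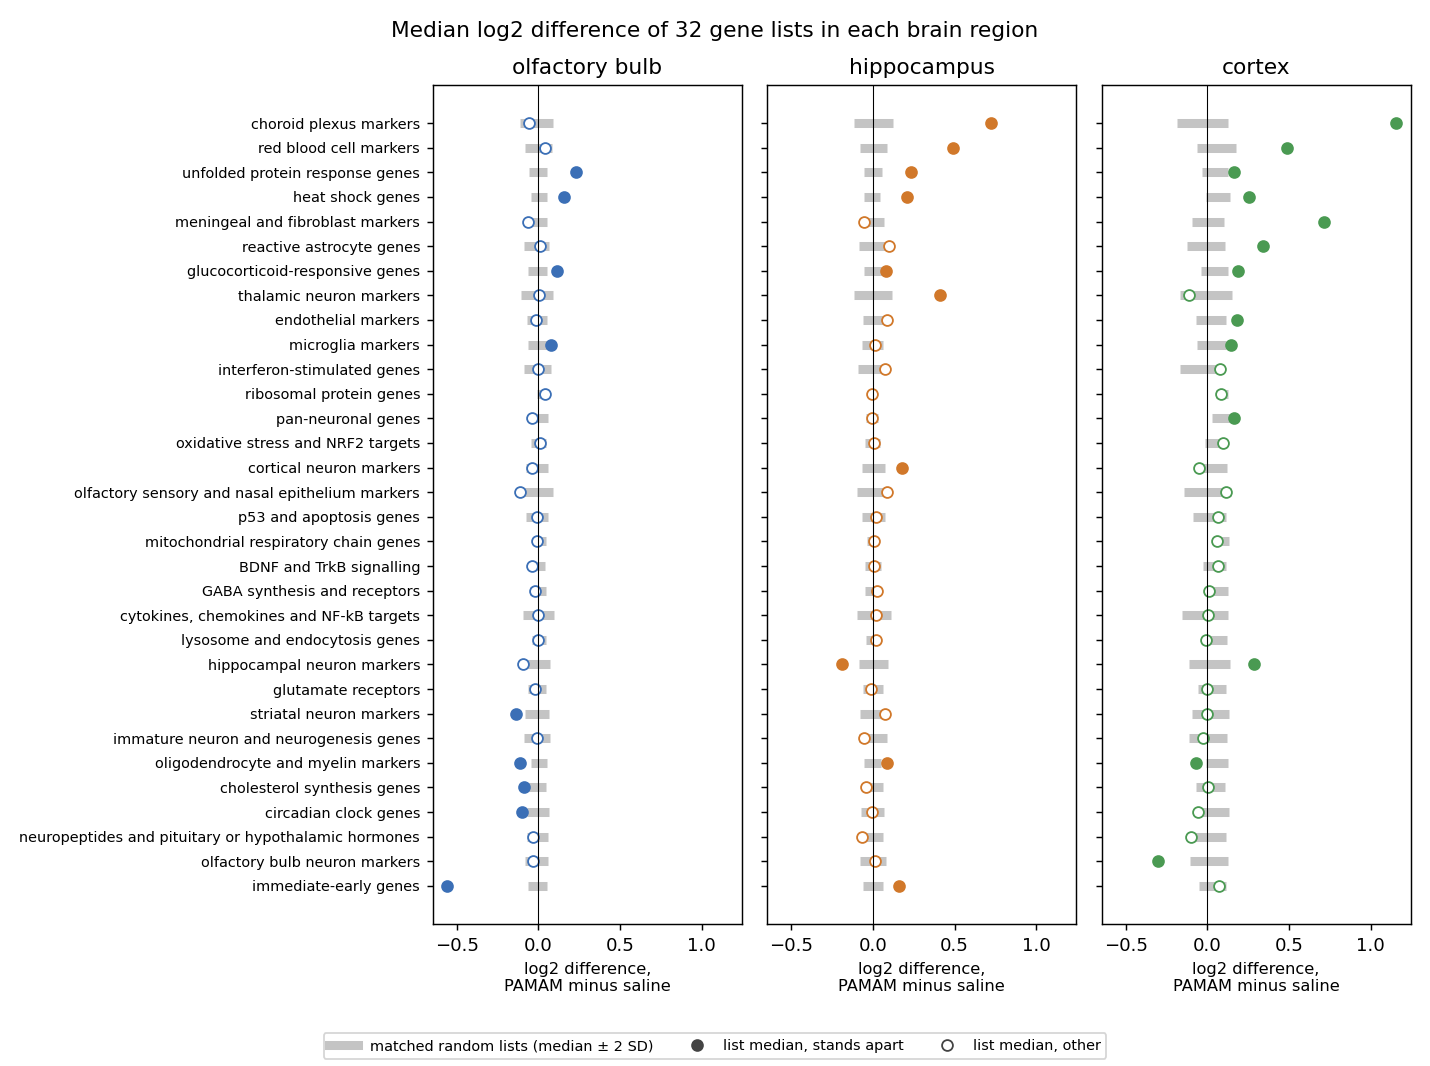
Median log2 difference between PAMAM and saline (x axis) of 32 gene lists (y axis) in the olfactory bulb, hippocampus and cortex. Points are list medians, filled where the list stands apart from 10000 matched random lists, and grey bars span 2 SD of the random medians to either side of their median; choroid plexus markers reach 0.72 in the hippocampus and 1.16 in the cortex, and immediate-early genes lie at -0.56 in the olfactory bulb.

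The last comparison asked which differences the 3 regions share. Genes of the unfolded protein response and heat shock were higher in each region, and 9 of 21 of the former rose in a limma fit over the 6 arrays with region as a block, adjusted over the list alone: Calr, Creld2, Hsp90b1, Hspa5, Manf, Pdia4, Pdia6, Sdf2l1 and Xbp1 (smallest adjusted p 0.00779). Over the regions Sdf2l1 was higher by 0.81 with a standard error of 0.07, and Hspa5 by 0.55 with a standard error of 0.07, each in 3 of 3 regions. Of 18 heat shock genes, Hspa1a, Hspb1 and Hsph1 rose, adjusted over the list alone (smallest adjusted p 0.0366). Of 19 circadian clock genes, Arntl, Nfil3 and Per2 rose in the limma fit, adjusted over the list alone (smallest adjusted p 0.0285). The clock output Dbp and the repressors Ciart and Nr1d1 fell in the same way. Nr1d1 differed by -0.52, -0.42 and -0.44 in the olfactory bulb, hippocampus and cortex, and Dbp by -0.57, -0.39 and -0.32. Of 16 striatal markers Drd2 alone fell (smallest adjusted p 0.0175, adjusted over the list alone; -0.58 over the regions), and in the other 28 lists 0 genes passed in that way. The adjustment was made within each list and not over the lists, so some lists can give a call by chance. Adjusted over all genes tested 0 passed, so the rises and falls named here hold within their lists only. Drd2 is also dim in the olfactory bulb.

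**Figure D4:**
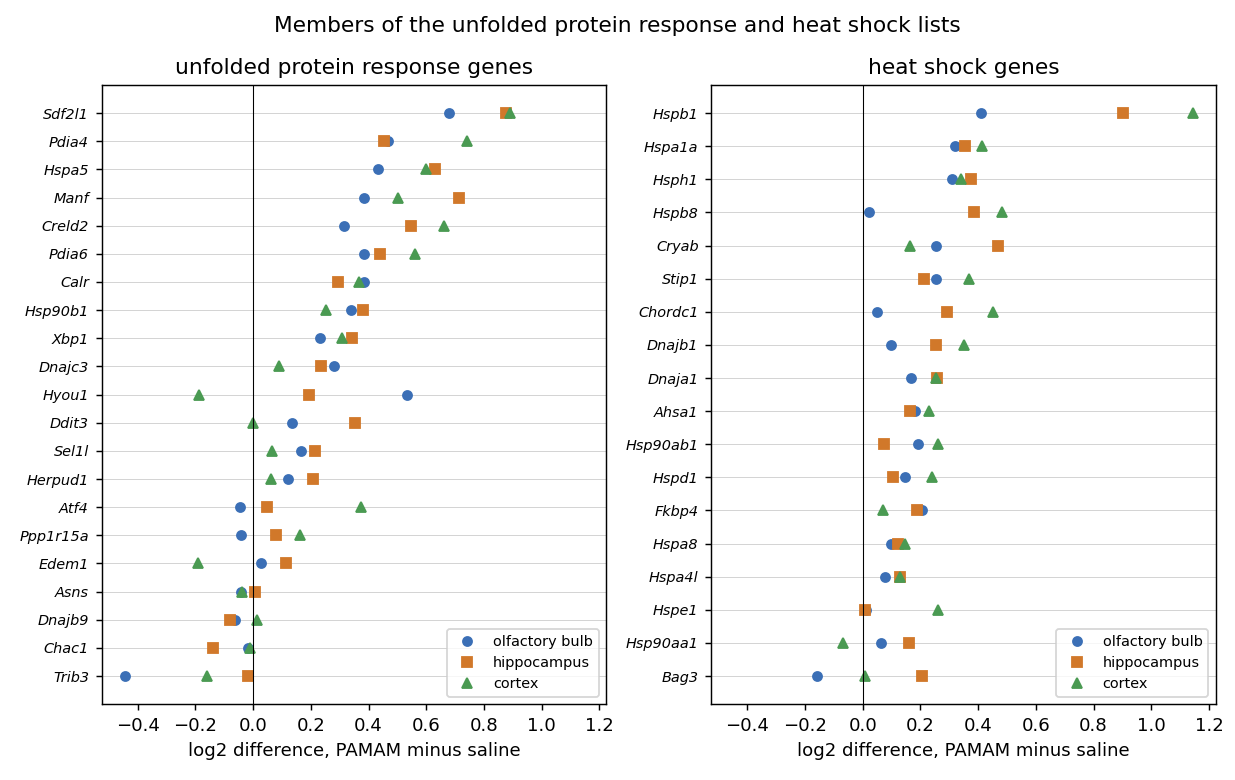
Log2 difference between PAMAM and saline (x axis) of each member (y axis) of the unfolded protein response and heat shock lists, with 1 point per region. Sdf2l1 lies at 0.68, 0.88 and 0.89 and Hspb1 at 0.41, 0.90 and 1.14 in the olfactory bulb, hippocampus and cortex, while Trib3 lies at -0.45, -0.02 and -0.16.

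Over all 23337 genes tested, limma called 0 genes, with 629 higher and 889 lower at an unadjusted p under 0.05 and a smallest adjusted p of 0.739, which ranged from 0.146 to 1 over the alternatives. The smallest unadjusted p belonged to the elongation factor gene Tcea3 (0.78), followed by Sdf2l1, Cenph (-0.59) and Drd2. Whether the regions came from the same mice is not given in the labels. If they did, the p-values of this fit are too small, also for the lists. The counts adjusted over the list alone fell when a region was left out. Without the hippocampus 0 genes of the unfolded protein response passed, and without the cortex 4. Without the olfactory bulb 1 heat shock gene passed, and without either other region 0. Such fits have fewer residual degrees of freedom than the 2 of the full fit. Lost calls thus do not show that a result rested on a single region. For the clock list 0 passed whichever region was left out.

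At the 2-fold threshold, 21095 genes were measured in every region and 1 of them was higher in all 3: a long noncoding RNA probe at mm9 chromosome 19, 5834543 to 5834602, with 1.06, 1.06 and 1.03 in the olfactory bulb, hippocampus and cortex. Other probes of this transcript gave 1.27 to 1.30, 1.07 and 0.69 to 0.78. The olfactory bulb and hippocampus shared 8 lower genes, against 0.0191 for independent lists, of which 6 were the near-identical Mup4, Mup5, Mup9, Mup17, Mup18 and Mup19. The hippocampus and cortex shared 3 higher genes, against 0.238: Cdkn1a (1.31 and 1.59), Inhba (1.18 and 1.30) and the noncoding RNA. The olfactory bulb and cortex shared Xlr3b, at -1.49 and -1.30. Across 12573 brighter genes the differences correlated with r = 0.197 between olfactory bulb and hippocampus, 0.0309 between olfactory bulb and cortex and 0.108 between hippocampus and cortex. These correlations are across genes, which are not independent replicates.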

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

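No test was run on the differences in this part. Each item is a result whose direction was opposite in 2 regions, and each region has 1 array per treatment, so the difference between regions was not tested.

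Immediate-early genes had a median of 0.16 in the hippocampus and -0.56 in the olfactory bulb, a difference of 0.72, which was picked out because the list lay above matched random lists in one region and below them in the other. Its members did not all go opposite ways: Fos (-0.36 in the hippocampus and -1.04 in the olfactory bulb), Npas4 (-0.63 and -1.13), Btg2 (-0.43 and -0.81), Nr4a3 (-0.36 and -1.24), Ier2 (-0.31 and -0.70), Egr4 (-0.25 and -1.49) and Junb (-0.22 and -1.36) were lower in both. The hippocampal mean was 0.05, and with normexp background its median (0.06) no longer stood apart. For the same reason as immediate-early genes, hippocampal neuron markers were picked out, at 0.29 in the cortex and -0.19 in the hippocampus, 0.47 apart. Oligodendrocyte and myelin markers were at 0.09 in the hippocampus against -0.11 in the olfactory bulb and -0.07 in the cortex, 0.20 and 0.16 apart. Lbhd2 differed at least 2-fold in opposite directions, at 1.25 in the hippocampus and -1.66 in the cortex, 2.91 apart. None of these differences was tested, and no explanation was weighed for them.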

How the results depend on the processing

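The counts without choroid plexus, meningeal and red blood cell lists were chosen after seeing the data, and all other alternatives before. Across the alternatives, 172 counts and main values stayed within 1.5 times their value or within their spread, and 68 moved further. Counts have no sign and could not reverse, and unchanged counts of 0 are among those that stayed. Of the region marker medians, which could reverse, 0 did. The cortical balance of higher and lower genes did turn, from 76 and 90 to 97 and 65 with quantile normalisation. Counts of genes at least 2-fold different are given as higher and lower in the olfactory bulb, hippocampus and cortex, then as genes at least 2-fold higher in 2 or more regions, genes at least 2-fold lower in 2 or more regions and genes at least 2-fold different the same way in all 3 regions; the main counts were 12 and 48, 130 and 15, 76 and 90, 3 and 9, and 1. A 1.5-fold threshold, looser by construction, gave 117 and 316, 521 and 165, 389 and 603, 46 and 37, and 7. A 3-fold threshold gave 4 and 13, 48 and 1, 14 and 25, 0 and 1, and 0. Without a filter on dim probes, which admits more genes, they were 779 and 913, 1384 and 569, 824 and 1230, 255 and 215, and 18. Brighter genes only, fewer genes by construction, gave 5 and 17, 29 and 3, 21 and 13, with 1 lower in 2 or more regions and 0 in all 3. Normexp background gave 6 and 19, 46 and 4, 24 and 19, with 3 lower in 2 or more regions and 0 in all 3; the cause was not tested. With the median of all probes of a gene, 0 differed in all 3. Genes passing limma adjusted over the list alone numbered 9 for the unfolded protein response, 3 for heat shock and 6 for the clock. Leaving out each region in turn, which also leaves fewer residual degrees of freedom, gave 0 to 6, 0 to 1 and 0 to 0. Without a region block they were 4, 0 and 0. Heat shock genes passing were 10 with brighter genes only and with normexp background, and 0 without a filter on dim probes, where 0 clock genes passed; 3 clock genes passed with the median of all probes; the cause was not tested. Lists below matched random lists numbered 5, 1 and 2 in the olfactory bulb, hippocampus and cortex; with wider percentile limits, looser by construction, 8, 2 and 4; with brighter genes only, 3 in the hippocampus and 1 in the cortex; without a filter on dim probes, 2 in the hippocampus; and with quantile normalisation, 3 in the olfactory bulb. The median SD between spots was 0.0882 over all repeated probes, dim ones included, against 0.0670. In all alternatives, limma over all genes called 0. Of list medians that stood apart, 32 of 32 did so with median centring, the deposited table and no filter, 31 of 32 with members measured on both arrays, 28 of 32 with quantile normalisation and with the median of all probes, 27 of 32 with normexp background and 27 of 31 with brighter genes only, and 0 changed sign. Of 243 values of named genes, 111 moved by more than spot noise with normexp background, 14 with quantile normalisation and 0 with median centring or the deposited table; 21 of 214 moved with the median of all probes, and 0 of those at least 2-fold different changed sign. No scaling moved the median of all genes by over 0.1. The genes expected from spot noise are all dim.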

Other observations

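The tests of other tissue, body temperature, time of day, choroid plexus, nasal tissue and liver transcripts in this part were chosen after the patterns they bear on were seen, the liver test before its own median was computed, and that of other splits before its result was seen.

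Some hypothalamic peptide genes, named here after their values were seen, were much lower with PAMAM in the cortex. Whether the saline and PAMAM samples held different amounts of neighbouring tissue was not tested for these genes. Their differences are thus not shown to be a response of the cortex. Besides Oxt (-3.47) and Avp (at least 16.4-fold lower), Trh differed by -1.04, the melanin-concentrating hormone gene Pmch by -0.74 and the orexin gene Hcrt by -0.35. Of the 27 members of their list well above background on at least 1 cortex array, 14 were lower and 13 higher, among the latter Grp at 0.75 and Scg2 at 0.45. In the hippocampus Pmch was at -1.17, Avp at -0.91, Cartpt at -0.61 and Hcrt at -0.42. In the olfactory bulb Avp was at least 5.05-fold lower and Agrp at -0.69, but Oxt at 0.44. Crh was higher in each region, by 0.54, 1.23 and 0.56 in the olfactory bulb, hippocampus and cortex, and the hippocampal dynorphin gene Pdyn by 0.77. The list of neuropeptide and pituitary or hypothalamic hormone genes as a whole had medians of -0.03, -0.07 and -0.10 and did not stand apart from matched random lists.

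Several large groups of brain genes differed little. In the olfactory bulb, hippocampus and cortex, glutamate receptor genes had medians of -0.02, -0.01 and 0.00, GABA genes of -0.02, 0.03 and 0.01, immature neuron genes of -0.01, -0.05 and -0.03, and p53 and apoptosis genes of -0.01, 0.02 and 0.07. Mitochondrial respiratory chain genes had medians of -0.01, 0.01 and 0.06, ribosomal protein genes of 0.04, -0.01 and 0.09, and lysosome and endocytosis genes of 0.00, 0.02 and -0.01. None of these lists stood apart in any region. Within the p53 list, Cdkn1a was at 0.20, 1.31 and 1.59, while the other targets Mdm2 (0.04, 0.15 and 0.09) and Phlda3 (-0.08, -0.15 and -0.12) differed little.

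Heat shock and unfolded protein response genes were higher with PAMAM in all 3 regions. In the olfactory bulb, choroid plexus, meninges or red blood cells in the PAMAM sample are argued against: the largest of the choroid plexus, meningeal and red blood cell medians lay 0.946 SD above matched random lists there, against 6.0 SD for heat shock and 8.50 SD for unfolded protein response genes. In the hippocampus and cortex it stays open, since the lowest of the choroid plexus and red blood cell medians lay 7.35 SD above. A higher body temperature of the PAMAM mice is a candidate explanation, since the cold-inducible Rbm3 and Cirbp were lower in all 3 regions, with -0.257 for Rbm3 in the cortex the smallest difference. Another is a different time of day at collection, since clock gene differences correlated across 19 genes between regions. With hippocampus and cortex r was 0.859, at percentile 99.77 of random lists (upper limit 0.675). With olfactory bulb and hippocampus it was 0.768, at percentile 98.5 (upper limit 0.715). With olfactory bulb and cortex it was 0.646, at percentile 97.78 and close to the upper limit of 0.638. Some random lists thus reached higher correlations. Only hippocampus and cortex lay beyond the percentile limits used above for list medians. Mice shared between regions might give the same correlations. A response to PAMAM itself remains open and untested.

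Choroid plexus markers were higher with PAMAM in hippocampus and cortex. If more choroid plexus was dissected, the signal added per gene should correlate between the regions. Across the 18 genes with added signal in both regions it did so with r = 0.897, but with 0.776 without Ttr. The latter, a condition added after the value was seen, fell short of the bound of 0.8. A response that raised these genes alike in both regions could give such a correlation too, so it does not part the explanations. A response of choroid plexus cells would need a sample of that tissue, of which there are 0 arrays. Among markers of other tissue, thalamic ones were higher in 9 of 11 members in the hippocampus but 4 of 12 in the cortex. Meningeal ones were higher in 21 of 22 in the cortex but 8 of 22 in the hippocampus. The explanations for the choroid plexus markers were not tested against these values and cannot be told apart here.

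Major urinary protein and Serpina1 genes were lower with PAMAM in the olfactory bulb. Nasal tissue in the saline sample failed the bound written for it, since nasal epithelium markers had a median of -0.114 there, smaller than the difference looked for. That bound was written after the results were seen, and the median lay more than 2 SD below matched random lists, in the direction that nasal tissue predicts, with 13 of the 17 markers lower, so a small amount of nasal tissue is not ruled out. Liver RNA in the saline sample is another candidate explanation that cannot be told apart from a response: 16 measured liver transcripts, with none of the Mup or Serpina1 genes among them, had a median of -0.874 in the olfactory bulb (13 lower), between bounds set before that median was computed but after the Mup and Serpina1 differences were seen, with -0.23 in the hippocampus and -0.04 in the cortex. Ambp, Ahsg and the albumin gene Alb were at least 7.41-fold, 7.08-fold and 4.83-fold lower in the olfactory bulb, each well above background in the saline array alone.

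For the shared difference over the regions, limma called 0 genes in the real split of the 6 arrays and at most 0 in the other splits, so all 10 of the 10 splits gave as many. With 0 in the real split this was bound to be so, and the count tests nothing; 10 splits are also too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 1518 genes and the other splits from 541 to 3052, the highest in 2 splits that part only 1 region's pair. The other splits that part the pair of every region gave 846, 942 and 1002.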
